A study of Mus musculus with 5 samples.

How the data were processed

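Libraries of mouse colon RNA were analysed, 2 from vehicle-treated and 3 from propyzamide-treated mice, each from a piece of frozen colon taken 3 days after TNBS. Per the labels' protocols, RNA was extracted with Trizol and libraries were made by the SMART-Seq2 method, which amplifies full-length cDNA. The labels describe each sample as a treated mouse but do not exclude shared animals, so p-values measure the spread between these samples. The segment of colon, the dose and whether the counting used strand are not given in the sources used here.

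The authors deposited 1 RSEM table per library with the estimated count, the TPM and the FPKM of each transcript, per the file headers. The deposited tables also give each transcript's percent of its gene's expression, per the file headers. The FPKM and percent columns were not used here. The tools RSEM and kallisto and the build GRCm38 are named, without versions or roles, per the submitters' processing notes. The aligner settings and the annotation release are not given in the sources used here. RSEM divides reads among transcripts, so genes with near-identical copies, overlapping genes and antisense partners can share counts.

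The authors' estimated counts of 142647 transcripts were summed to 55471 genes and rounded to whole numbers. Symbols were found for 99.4% of the gene identifiers, and 99.6% were found in the GENCODE M21 annotation of GRCm38, from which coordinates and biotypes were taken. Totals ranged from 1573700 to 2706885 counts per library, of which 823540 to 1328793 lay outside rRNA-like loci (AY036118, CT010467.1 and Gm26917) and mitochondrial genes. One count therefore equals 0.340 to 0.609 CPM, and the floor of 3 counts over a group is 0.718 CPM in vehicle and 0.459 CPM in propyzamide. Floors and intervals cover counting error only and treat each read as independent. These reads carry no molecular identifiers, so copies made by amplification are counted too, and the intervals may be too narrow.

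Genes were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, quasi-likelihood fit and test, Benjamini-Hochberg adjustment and a threshold of 0.05. All 5 libraries entered 1 model with the group as its term. CPM values use TMM-scaled library sizes, and the SE of a log2 fold change was taken from the quasi-likelihood F statistic. Transcripts were tested in the same way on rounded counts. Gene lists, 34 in all, were tested with camera and fry from limma 3.58.1 where at least 3 members were tested. Camera was run with a preset correlation of 0.01 and with the correlation estimated from the data, and adjustment was over 27 lists. DESeq2 1.42.0 was an alternative.

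The gene lists, the tests, the rule for naming genes and all but 4 of the alternatives were fixed before the data were examined. The rule took the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2, no overlap between the groups in CPM, and no predicted, clone, pseudogene, immunoglobulin or T-cell receptor name. It added up to 4 members of smallest p from each list described, and a fixed set of aryl hydrocarbon receptor, NF-kB, C/EBP, cytokine and inflammation genes whatever their values. One gene that the rule named is not reported here.

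The gene and list steps were tested on simulated counts with 200 changed genes among 12024. The counts were drawn from the real means and library sizes and the trend of dispersion with level. Genes were drawn independently, so gene-specific spread and correlation between genes were left out, and recovery in the real data may be lower. For the same reason the preset correlation of the list step was not tested. Of the genes changed 2-fold, 4-fold and 8-fold, 1.49%, 47.8% and 89.4% were recovered, and 3.16% of the calls were false. For transcripts, among 16682, the recovered shares were 0%, 0% and 10.6%.

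Alternatives were other scalings, filters, DESeq2, limma on log2(TPM + 1) and log2(TPM + 0.1) of the authors' TPM values, an offset for average transcript length, a replicate block, each library left out in turn, gene classes removed, and a threshold of 0.1. After the data were seen, 4 more were added: removal of rRNA-like and mitochondrial genes, protein-coding genes only, genes above background only and subtraction of background. Background was estimated per library from the counts per kilobase of 1972 olfactory and vomeronasal receptor genes, and a gene counted as above it where its higher group's mean CPM was at least 5 times the level expected for its length. No pair of libraries was a duplicate: the chi-square per degree of freedom lay between 11.9 and 25.8 over genes with a summed count of at least 10.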

Results

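RNA sequencing was carried out on pieces of colon from male C57BL/6 mice, 11 weeks old, taken 3 days after colitis had been induced with TNBS (trinitrobenzene sulfonic acid, a hapten that provokes inflammation of the colon). Mice received either vehicle (2 libraries) or propyzamide (3 libraries), a herbicide that blocks microtubule assembly in plants. The series title presents the herbicide as tested in a model of inflammatory bowel disease, and 1 comparison follows from that design: propyzamide against vehicle. The total estimated count per library was 1573700 and 2258237 in vehicle, and 2706885, 2441897 and 1882235 in propyzamide. Colon from mice without TNBS was not analysed here.

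The libraries differed in composition. Loci that resemble ribosomal RNA took 26.3% and 43.6% of the counts in vehicle and 40.9%, 36.7% and 41.6% in propyzamide, and the mitochondrial genome took 9.998% and 19.7% against 10.01%, 21.6% and 14.6%. Wilson 95% intervals of these shares reached at most 0.0704 percentage points to either side and cover counting error only. After all libraries were thinned to 823540 counts outside these genes, 30426 and 27496 genes had a count in vehicle, against 17215, 19248 and 16833 in propyzamide. Olfactory and vomeronasal receptor genes, which serve smell and pheromone sensing, had a count after thinning for 63.3% and 52.7% of the 1972 genes in vehicle, and for 8.01%, 37.9% and 15.8% in propyzamide, with Wilson 95% intervals of up to 2.20 percentage points to either side. The groups also carried different second index sequences, 1 in vehicle and 1 in propyzamide with 0 shared, so any difference between index batches and the treatment cannot be told apart.

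**Figure D1:**
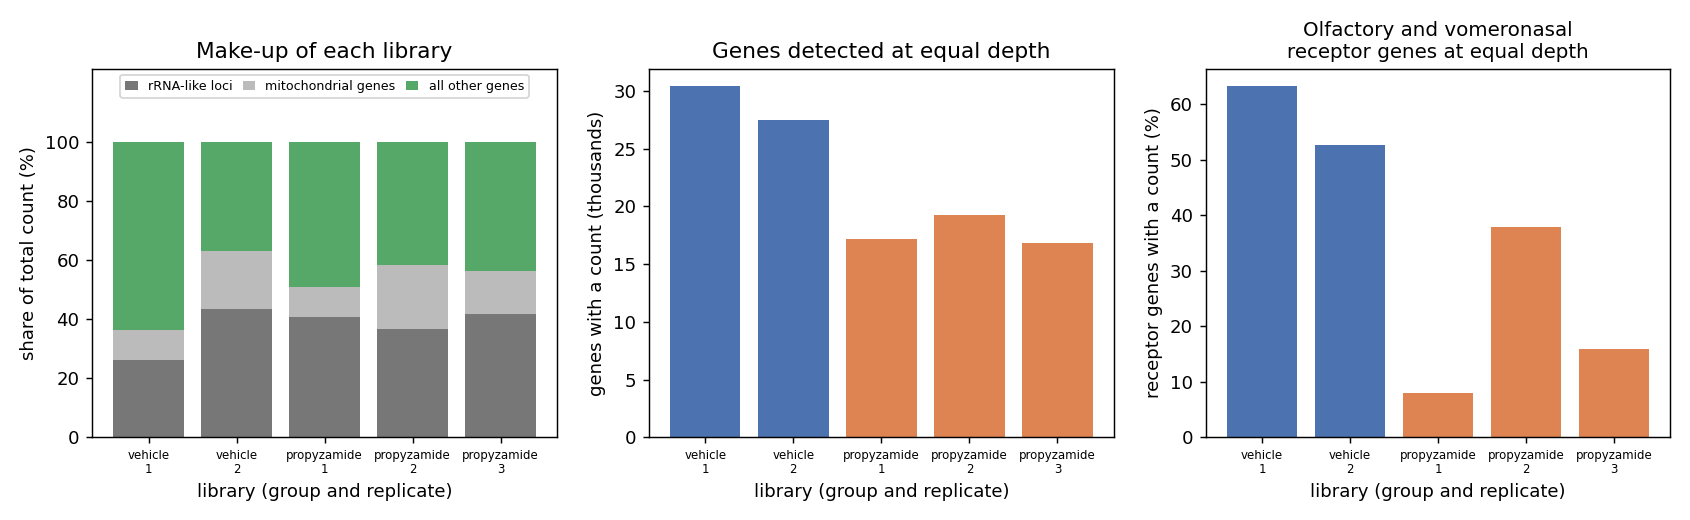
Share of the total count (%) taken by rRNA-like loci, mitochondrial genes and all other genes in each of the 5 libraries (left), genes with a count after thinning to 823540 counts (middle) and percent of 1972 receptor genes with a count after thinning (right), with vehicle in blue and propyzamide in orange. Both vehicle libraries, at 30426 and 27496 genes, lay above the 3 propyzamide libraries, at 16833 to 19248.

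Of the genes that rose in propyzamide, Slc9a3, the apical sodium-proton exchanger of absorptive cells, went from 6.45 ± 2.11 CPM (SD, n = 2) to 234 ± 90.4 CPM (SD, n = 3), with an edgeR adjusted p of 0.00204. Fabp2, the intestinal fatty acid binding protein, rose from 5.14 ± 3.26 to 506 ± 308 CPM (edgeR adjusted p = 0.00231). Reg3b, an antimicrobial lectin of gut epithelium, was at 0 counts in both vehicle libraries and at 26.2, 116 and 189.9 CPM in propyzamide (edgeR adjusted p = 0.00605, a call lost without vehicle replicate 1). Against a floor of 3 counts over the vehicle group Reg3b was 131-fold higher, and its exact counting interval began at 106-fold. In the other direction Hoxd13, a homeobox gene of posterior body patterning, fell from 33.5 and 51.6 CPM in vehicle to 0 counts in the 3 propyzamide libraries (edgeR adjusted p = 0.00217). Against a floor of 3 counts over the propyzamide group Hoxd13 was 89.6-fold lower, and its exact counting interval began at 72.1-fold. Mptx1, a mucosal pentraxin, fell from 476 ± 378 to 5.07 ± 5.42 CPM, and Reg4, a secreted lectin, fell from 250.3 ± 251 to 5.59 ± 2.73 CPM (edgeR adjusted p = 0.00413 for each). The call for Mptx1 was lost with limma on log2(TPM + 0.1) (limma adjusted p = 0.353).

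The 10 genes with the largest increases were Reg3b, Prap1, Fabp2, Tmigd1, Cfd, Alpi, Pdk4, Slc9a3, Ctxn3 and Slc10a2. Slc10a2 encodes the ileal bile acid transporter and rose by 5.05 ± 0.83 (log2, SE), with an edgeR adjusted p of 0.0136. Alpi, the intestinal alkaline phosphatase, had 2 counts in vehicle and 178 in propyzamide, a ratio of 56.9 with an exact counting interval of 15.5 to 474. Cfd, the complement factor secreted by fat cells, rose by 5.90 ± 1.29 (log2, SE; edgeR adjusted p = 0.0417) and was at 192 CPM in propyzamide replicate 3 against 17.3 and 26.7 CPM in the other two. Pdk4, a kinase that restrains glucose oxidation, had 1 count in vehicle and 64 in propyzamide (edgeR adjusted p = 0.0478), a ratio of 41.0 with a counting interval of 7.09 to 1642. Prap1 was at 0 counts in both vehicle libraries, 14.3-fold higher in propyzamide against the floor of 3 counts, with an exact counting interval that began at 11.3-fold. Tmigd1 and Ctxn3 rose by 6.45 and 5.13 on the log2 scale, with edgeR adjusted p of 0.00217 and 0.00759. Without vehicle replicate 1 the calls for Reg3b, Prap1, Cfd, Pdk4, Ctxn3 and Slc10a2 were lost (edgeR adjusted p 0.0619 to 0.364). Without vehicle replicate 2 those for Prap1, Cfd, Alpi, Pdk4, Ctxn3 and Slc10a2 were lost (0.0685 to 0.241), and without propyzamide replicate 3 that for Cfd (0.0736). Cfd had 0 counts in vehicle replicate 1 and stood at a fitted 10.45 without vehicle replicate 2. Both vehicle counts of Alpi were in replicate 1, and its fitted log2 fold change of 5.66 was 8.79 without that library and 8.77 with background subtracted. Those for Prap1 and Pdk4 were also lost at 10 CPM in 2 samples (0.0520 and 0.0723) and with background subtracted (0.0604 and 0.0656), and that for Pdk4 above background (0.0559). That for Cfd was also lost above background (edgeR adjusted p = 0.0504), with background subtracted (0.0584), with DESeq2 (0.0589) and with limma on log2(TPM + 0.1) (0.252).

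The 10 genes with the largest decreases were Hoxd13, Mptx1, Fxyd4, Duxf3, Reg4, B3gnt7, Slc37a2, Ttr, Tgm3 and Lrmp. Fxyd4, a regulator of the sodium pump, changed by -5.81 ± 0.81 (log2, SE; edgeR adjusted p = 0.00605). B3gnt7, a glycosyltransferase, fell from 297 ± 11.6 to 10.9 ± 12.9 CPM, and Tgm3, a transglutaminase, fell from 236 ± 28.7 to 11.5 ± 9.46 CPM. Slc37a2, a sugar phosphate transporter, changed by -4.50 ± 0.67, Ttr, the thyroid hormone carrier transthyretin, by -4.36 ± 0.73, and Lrmp by -4.24 ± 0.90 (log2, SE). Duxf3, with 122 counts in vehicle and 3 in propyzamide (ratio 63.6, counting interval 21.2 to 312), belongs to a repeated gene family whose copies share reads, so its assignment is uncertain. Without vehicle replicate 1 the calls for Duxf3, Ttr and Lrmp were lost (edgeR adjusted p 0.131 to 0.412), and without vehicle replicate 2 those for Fxyd4, Duxf3, Slc37a2, Ttr and Lrmp (0.0503 to 0.174). Without propyzamide replicate 2 the call for Lrmp was lost (0.0505), and without propyzamide replicate 3 those for B3gnt7 (0.0540) and Lrmp (0.0742). Without propyzamide replicate 1 Ttr stood at -6.75 and Lrmp, then at 0 counts in propyzamide, at a fitted -8.27. The 3 propyzamide counts of Duxf3 were all in replicate 2, without which its fitted -5.76 was -8.98. The calls for Mptx1 and Fxyd4 were lost with limma on log2(TPM + 0.1) (limma adjusted p = 0.353 and 0.245). That for Slc37a2 was lost with DESeq2 (adjusted p = 0.0737) and that for Lrmp with background subtracted (edgeR adjusted p = 0.0584). On the GRCm38 build and its GENCODE annotation, Slc9a3 spans chromosome 13 from 74121457 to 74169442, Reg3b chromosome 6 from 78370657 to 78373466, Hoxd13 chromosome 2 from 74668310 to 74671599, and Mptx1 chromosome 1 from 174330518 to 174332873.

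**Figure D2:**
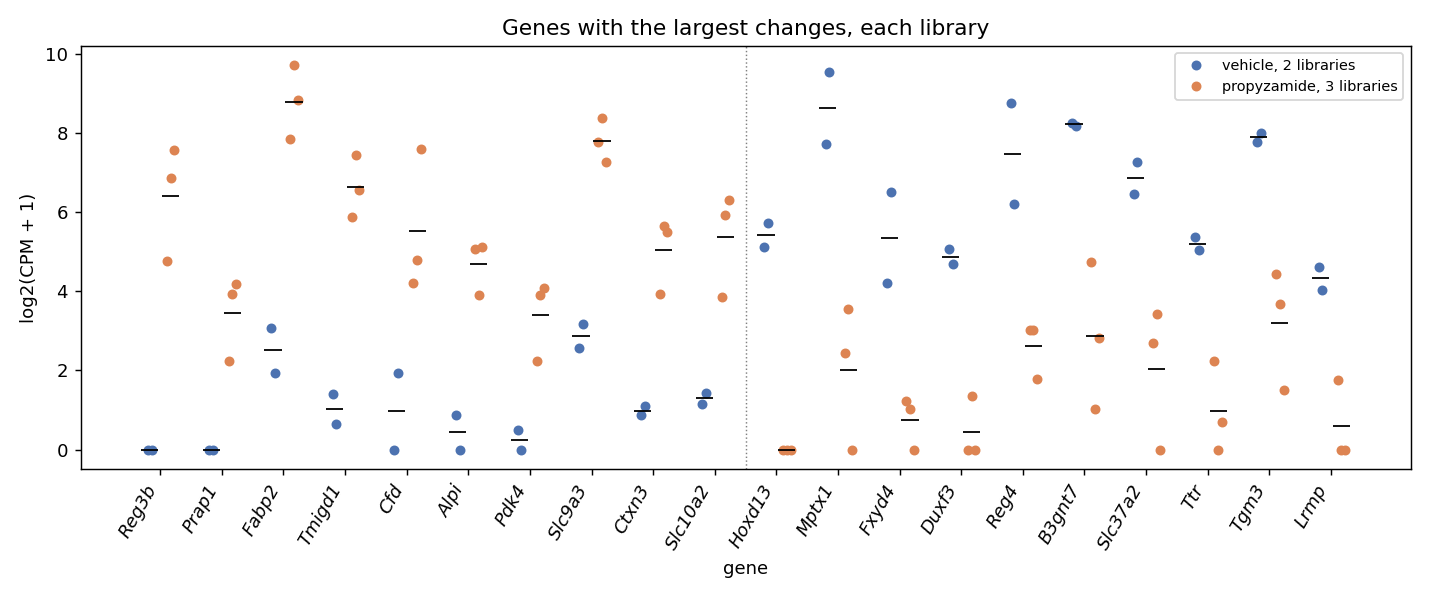
Level of the 20 genes with the largest changes, as log2(CPM + 1), with 1 point per library (vehicle blue, n = 2, and propyzamide orange, n = 3) and a black line at each group's mean of the plotted values. The libraries of the groups did not overlap for any of these genes, which the naming rule required, and Hoxd13 lay at 0 in all 3 propyzamide libraries.

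Across the transcriptome, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found 229 of 12024 tested genes changed at an adjusted p under 0.05, of which 83 were higher and 146 lower in propyzamide (63.8% lower). All 229 were separated between the groups in CPM, and among all tested genes 37.5% were separated, where chance gives 20% for a single gene. All genes share the same libraries, so their share can lie far from 20% without an effect of treatment. The balance of directions varied with the setting. It was 79 higher and 235 lower with upper-quartile scaling (74.8% lower), and 92 and 596 with limma on log2(TPM + 1) (86.6% lower). With limma on log2(TPM + 0.1) it was 51 and 288 (85.0% lower), with DESeq2 260 and 305 (54.0% lower), and it turned to 35 higher and 20 lower without vehicle replicate 2 (36.4% lower). The limma runs had no scaling between libraries beyond TPM. In them the median log2 fold change of all genes was -0.39 at pseudocount 1 and -0.47 at 0.1, against -0.018 in the main test. Of the 146 lower genes, 32 had 0 counts in all 3 propyzamide libraries, and of the 83 higher genes 2 had 0 counts in both vehicle libraries. Of the lower genes, 39 lay under 5 times the larger of the groups' background levels set by the receptor genes, against 0 of the 83 higher genes. The count rests on few libraries: it was 36 without vehicle replicate 1, 55 without vehicle replicate 2, 499 without propyzamide replicate 1 and 78 without propyzamide replicate 3. Of the 20 genes named above 11 and 9 passed without vehicle replicates 1 and 2, all 20 keeping their direction. A change of direction was unlikely there by construction, since the naming rule required groups without overlap. At the transcript level edgeR called 0 of 16682 transcripts, with 1696 at an unadjusted p under 0.05, and DESeq2 called 441.

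Among the fixed gene lists, markers of absorptive colonocytes had a median log2 fold change of 0.66 over 18 tested members, 11 of them positive and 7 negative. That median was 0.32 without vehicle replicate 1, 1.16 without vehicle replicate 2 and 0.16 without propyzamide replicate 2. Over all genes 3 of these members rose, 0 fell and 15 did not pass, and 7 rose when adjusted over the list alone. Beside Slc9a3, Guca2a, the precursor of the gut peptide guanylin, rose from 256 and 251 CPM to 2863, 3843 and 2440 CPM (edgeR adjusted p = 0.00759). Cyp2c55, a cytochrome of the colon, stood at 2.22 ± 0.52 with an edgeR adjusted p of 0.0504, and passed in 7 of 19 alternatives. The call for Guca2a was lost without vehicle replicate 1 (edgeR adjusted p = 0.0559). The list passed camera's test with the preset correlation (adjusted p = 4.54e-05) but not with an estimated correlation (adjusted p = 0.310). Fry's directional test gave an adjusted p of 0.134, and its mixed test, for change in either direction, gave 0.00846. The xenobiotic metabolism list had a median of 0.47 over 16 members, of which Aldh1a1, a retinal dehydrogenase, rose by 3.38 ± 0.54 (edgeR adjusted p = 0.0119). The other 15 did not pass, while 4 rose adjusted over the list alone. The call for Aldh1a1 was lost without vehicle replicate 1 (edgeR adjusted p = 0.157) and vehicle replicate 2 (0.0995). The list's median was 0.83 without vehicle replicate 2, 0.73 without propyzamide replicate 1 and 0.31 without propyzamide replicate 2. Its camera adjusted p was 0.00929, and adjusted p = 0.310 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.61 with 0 of 18 members past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00110, and adjusted p = 0.310 with an estimated correlation).

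Goblet-cell markers had a median of -1.17 over 14 tested members, of which 1 fell, 0 rose and 13 did not pass, with 3 falling and 1 rising adjusted over the list alone. Best2, a chloride and bicarbonate channel of colonic goblet cells, changed by -3.74 ± 0.77 (log2, SE; edgeR adjusted p = 0.0339), whereas Clca1, a secreted goblet-cell product, stood at -2.98 ± 0.73 (edgeR adjusted p = 0.0521) and Retnlb at 2.13 ± 0.73 (edgeR adjusted p = 0.147), and these genes passed in 6 and 2 of 19 alternatives. Without vehicle replicate 1 Clca1 stood at -1.83 and Retnlb at 3.53, and without propyzamide replicate 1 Retnlb stood at 1.05 and Best2 at -5.74. With the average transcript length offset Clca1 stood at -1.52. Summed goblet markers varied within the groups, from 9444 to 3242 CPM in vehicle and from 752 to 6974 CPM in propyzamide. Stem-cell and crypt markers had a median of -0.77 over 10 members, of which Lgr5, the receptor that marks intestinal stem cells, fell by 3.50 on the log2 scale (SE 0.76; edgeR adjusted p = 0.0417) and 9 did not pass, with 4 falling adjusted over the list alone. Enteroendocrine markers had a median of -2.00 over 7 members, 0 past the threshold over all genes and 4 lower adjusted over the list alone, with Pyy, Chga, Chgb and Insl5 at -2.61, -2.16, -2.00 and -3.09. Without propyzamide replicate 1 Pyy, Chga and Insl5 passed at -3.52, -3.36 and -6.07, without propyzamide replicate 2 Pyy passed at -2.06, and without vehicle replicate 1 Chgb stood at -0.59. Over all alternatives these genes passed in 4, 4, 2 and 5. The vehicle libraries, in which these genes stood higher, also had the larger estimated background, at 9.61% and 7.36% of the counts outside rRNA-like and mitochondrial genes, against 0.477%, 4.91% and 1.81% in propyzamide. Camera with the preset correlation still called the goblet, stem-cell and enteroendocrine lists above background and with background subtracted. The call for Best2 was lost without vehicle replicate 1 (edgeR adjusted p = 0.392), vehicle replicate 2 (0.107) and propyzamide replicate 3 (0.0842). That for Lgr5 was lost without every library but propyzamide replicate 1 (edgeR adjusted p 0.0663 to 0.527), with background subtracted (0.0852) and with limma on log2(TPM + 0.1) (0.0614). Camera adjusted p were 0.00569, 0.00770 and 0.00618 for these 3 lists, and adjusted p = 0.586, 0.481 and 0.481 with an estimated correlation. Without vehicle replicate 1 the goblet and enteroendocrine lists missed camera's threshold (adjusted p = 0.420 and 0.101) and had medians of -0.12 and -0.91. Without propyzamide replicate 2 the goblet list missed it with a median of -0.77 (adjusted p = 0.116), and without a filter on low counts all 3 lists missed it (0.305, 0.186 and 0.305). Without propyzamide replicate 1 the medians of the goblet, enteroendocrine and stem-cell lists were -2.08, -3.44 and -1.27.

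Smooth-muscle markers had a median of 2.06 over 12 members, all of them positive, with 0 past the threshold over all genes and 10 adjusted over the list alone. Their median was 1.19 without vehicle replicate 1 and 3.90 without vehicle replicate 2. Synm, Synpo2 and Cnn1, which encode filament and actin-binding proteins of muscle, stood at 2.50, 2.31 and 2.23 on the log2 scale with edgeR adjusted p of 0.0504, 0.0575 and 0.0783, and passed in 10, 7 and 5 of 19 alternatives. Without vehicle replicate 2 they passed at 3.90, 3.88 and 3.90 (edgeR adjusted p = 0.0412, 0.0334 and 0.0334), and without vehicle replicate 1 Cnn1 stood at 1.47. Summed smooth-muscle markers were 549 CPM in vehicle replicate 1, 3624 in vehicle replicate 2, and 6146, 9668 and 10358 CPM in propyzamide. Adipocyte markers had a median of 2.85 over 7 members, of which Cfd and Cidec, a protein of fat droplets, rose and 5 did not pass, with 4 rising adjusted over the list alone. Their summed level was 56.2 and 48.2 CPM against 117, 167 and 489 CPM. Fibroblast and matrix genes had a median of 0.88 over 17 members, of which Tnc, the matrix glycoprotein tenascin-C, rose by 2.30 ± 0.44 (edgeR adjusted p = 0.0274), 16 did not pass and 6 rose adjusted over the list alone. The list's median was 0.42 without propyzamide replicate 3. The calls for Cidec and Tnc were lost without vehicle replicate 1 (edgeR adjusted p = 0.0599 and 0.236), vehicle replicate 2 (0.141 and 0.175) and propyzamide replicate 3 (0.0714 and 0.0736). That for Cfd was lost without these same libraries (0.364, 0.145 and 0.0736), and that for Cidec also without propyzamide replicate 2 (0.0505). The adipocyte median was 1.87 without a filter on low counts. With limma on log2(TPM + 0.1) the calls for Cfd, Cidec and Tnc were lost (limma adjusted p = 0.252, 0.136 and 0.209), and with limma on log2(TPM + 1) that for Tnc (0.173). With the length offset that for Cidec was lost (edgeR adjusted p = 0.0828), and with DESeq2, above background and with background subtracted that for Cfd (0.0589, 0.0504 and 0.0584). Camera adjusted p were 3.56e-09, 6.68e-06 and 3.91e-04 for muscle, fat and matrix, and adjusted p = 0.481, 0.310 and 0.579 with an estimated correlation.

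Tubulin genes, which encode the subunits of microtubules, had a median of 0.74 over 11 members. Tuba1a rose from 42.6 and 40.3 CPM to 92.4, 185 and 300 CPM (2.21 ± 0.49 on the log2 scale; edgeR adjusted p = 0.0438), 10 members did not pass, and 4 rose adjusted over the list alone. Tubb2a, Tubb6 and Tuba1c stood at 2.05, 1.73 and 1.23 with edgeR adjusted p of 0.0671, 0.0560 and 0.108, and passed in 4, 4 and 2 of 19 alternatives. These genes resemble one another in sequence, so reads shared between them add uncertainty. The list's camera adjusted p was 0.00120, and adjusted p = 0.310 with an estimated correlation. The call for Tuba1a was lost without vehicle replicate 1 (edgeR adjusted p = 0.331), vehicle replicate 2 (0.233), propyzamide replicate 2 (0.0613) and propyzamide replicate 3 (0.108). It was also lost at 10 CPM in 2 samples (0.0503), above background (0.0533), with background subtracted (0.0721) and with limma at pseudocounts 1 and 0.1 (0.161 and 0.225).

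Genes of the aryl hydrocarbon receptor, NF-kB and C/EBP pathways were followed whatever their values. Ahrr, the repressor of the aryl hydrocarbon receptor, was lower: it had 38 counts in vehicle and 1 in propyzamide, a ratio of 59.4 with a counting interval of 10.03 to 2407 (edgeR adjusted p = 0.0332), and its vehicle mean of 8.93 CPM was 5.01 times the expected background. The call was lost without vehicle replicate 1 (edgeR adjusted p = 0.430), vehicle replicate 2 (0.233), propyzamide replicate 2 (0.0522) and propyzamide replicate 3 (0.0697), and with background subtracted (0.0739). The receptor itself, Ahr, stood at 5.79 ± 1.76 CPM in vehicle and 7.90 ± 6.20 CPM in propyzamide (edgeR adjusted p = 0.822). Tiparp stood at 6.64 ± 0.56 and 9.48 ± 3.01 CPM (edgeR adjusted p = 0.697). The 4 tested AHR target genes had a median of 0.39 and a mean of -0.82 while camera's direction was up (adjusted p = 0.949), with 1 fallen over all genes, and 1 fallen and 1 risen adjusted over the list alone. Fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 0.00846. The list's median was 1.61 without vehicle replicate 1 and 0.067 without propyzamide replicate 1.

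Of the NF-kB genes, Nfkbia, Nfkb1 and Rela stood at 0.18 ± 0.39, -0.49 ± 0.38 and 0.10 ± 0.38 on the log2 scale, with edgeR adjusted p of 0.861, 0.543 and 0.932. Relb, Birc3 and Nfkb2, with Nfkb1 the members of smallest p in the NF-kB target list, stood at -1.10, -1.20 and -0.97. They were lower in each propyzamide library than in either vehicle library but did not pass (edgeR adjusted p = 0.173, 0.282 and 0.327). The NF-kB target list had a median of -0.17 over 13 members, 6 of them positive and 7 negative. In it 0 passed the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.565). Its median was -0.35 without vehicle replicate 1, 0.25 without vehicle replicate 2 and 0.021 without propyzamide replicate 1. The C/EBP and acute-phase list had a median of 0.66 over 12 members, of which Hp, the haemoglobin scavenger haptoglobin, rose by 4.18 ± 0.82 (edgeR adjusted p = 0.0283). The other 11 did not pass, and 2 rose adjusted over the list alone (camera adjusted p = 0.0772, and adjusted p = 0.586 with an estimated correlation). The call for Hp was lost without vehicle replicate 1 (edgeR adjusted p = 0.293), vehicle replicate 2 (0.195) and propyzamide replicate 3 (0.0714). The list passed camera without propyzamide replicate 1 (adjusted p = 0.00610), with a median of 0.996, and without a filter on low counts (adjusted p = 0.00224). Its median was 0.33 and 0.27 without propyzamide replicates 2 and 3, and 0.059 with the replicate number as a block. That block fit also leaves propyzamide replicate 3 out of the group effect. Saa3, an acute-phase protein, was at 202 CPM in propyzamide replicate 2 and at 4.08 and 19.5 CPM in the other two (edgeR adjusted p = 0.116), and passed in 4 of 19 alternatives, among them that without propyzamide replicate 1 (0.0137), while its log2 fold change of 4.30 was 1.56 without propyzamide replicate 2. Lcn2, an antimicrobial protein that marks gut inflammation, stood at 3.25 ± 3.43 CPM in vehicle and 10.4 ± 7.73 CPM in propyzamide (edgeR adjusted p = 0.360).

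Several cytokine and immune-cell genes had too few counts for the test. Ifng and Il17a had 0 counts in all 5 libraries. Tnf had 5 counts in vehicle and 1 in propyzamide, Il1b 4 and 9, Il6 13 and 1, Il22 2 and 0, Il10 1 and 0, Foxp3 10 and 9, S100a8 6 and 6, S100a9 10 and 4, Cebpb 2 and 16, Cyp1a1 6 and 2, and Cyp1b1 4 and 18. The counting interval of the ratio of vehicle over propyzamide excluded 1 for Il6 (20.3, interval 3.05 to 863) and S100a9 (3.91, interval 1.13 to 17.1), whose 10 vehicle counts were all in replicate 2. The vehicle mean of Il6, 3.07 CPM, was 3.75 times the expected background and so under the 5 times set for genes above background. That of propyzamide over vehicle excluded 1 for Cebpb (5.12, interval 1.203 to 45.9), and these intervals leave out the spread between libraries. For the others with a count the interval included 1, and a difference was not detectable at this depth, where 1 count equals 0.340 to 0.609 CPM. Of the T-cell markers 0 were tested, of the neutrophil, T helper and ILC, regulatory T-cell, mast-cell and tuft-cell lists 1 each, and of the red blood cell genes 2. Antigen-presentation genes had a median of -0.69 over 13 members, with 0 past the threshold over all genes and 2 lower adjusted over the list alone, H2-Ab1 and H2-Eb1 of the class II complex, which passed over all genes in 1 and 5 of 19 alternatives (camera adjusted p = 0.00770, and adjusted p = 0.579 with an estimated correlation). Dendritic-cell markers had a median of -2.86 over 3 members, with 2 lower adjusted over the list alone (camera adjusted p = 0.00770, and adjusted p = 0.310 with an estimated correlation). These included Siglech, which had 17 counts in vehicle and 0 in propyzamide (edgeR adjusted p = 0.0730) and passed in 3 of 10 alternatives. Siglech was 8.86-fold lower against the floor of 3 counts, and its exact counting interval began at 6.45-fold. The antigen-presentation list missed camera's threshold without vehicle replicate 1 (adjusted p = 0.113) and propyzamide replicate 1 (0.0594), and without a filter on low counts (0.163). Its median was -0.43 without vehicle replicate 1, -1.06 without vehicle replicate 2 and -1.035 without propyzamide replicate 3. The dendritic-cell list had 3 tested members in 7 of its alternatives.

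**Figure D3:**
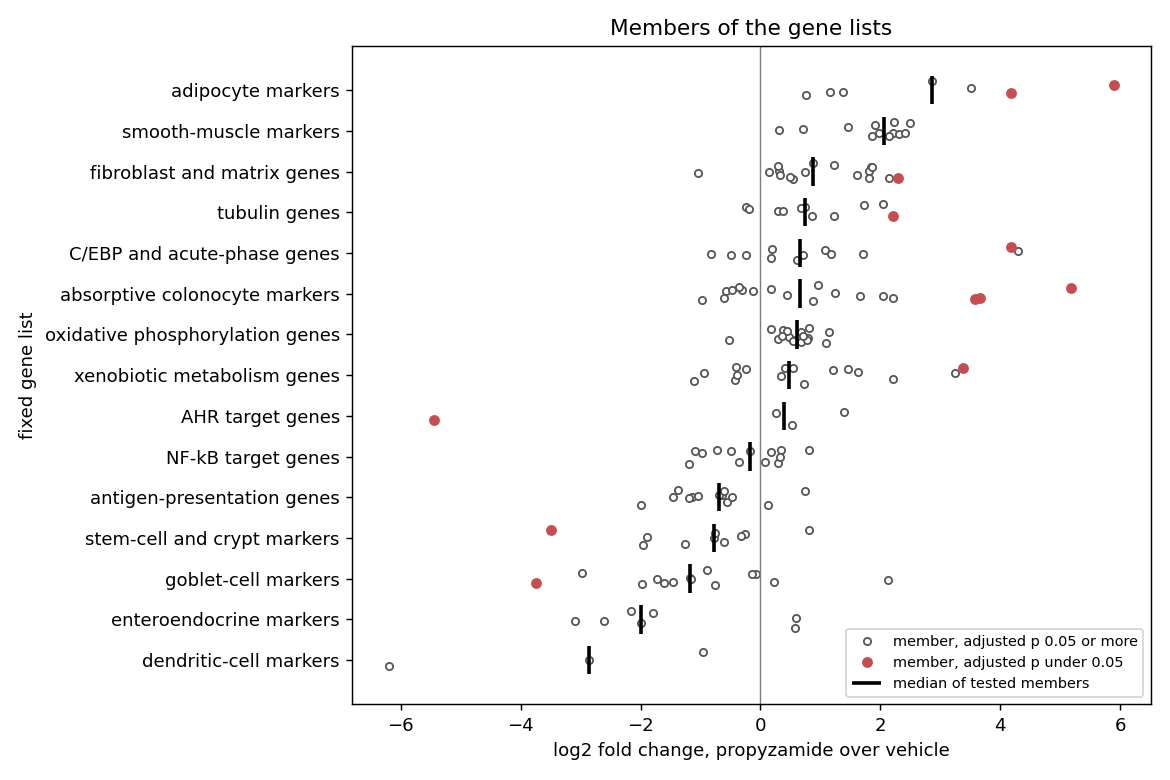
Log2 fold change, propyzamide over vehicle, of each tested member (points, red where the edgeR adjusted p was under 0.05) of 15 fixed gene lists, with the median as a black bar and Siglech, at 0 counts in propyzamide, at its fitted value. Adipocyte and smooth-muscle markers had medians of 2.85 and 2.06, and dendritic-cell and enteroendocrine markers of -2.86 and -2.00.

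Of the 27 lists with at least 3 tested members, 12 passed camera with the preset correlation, 7 higher and 5 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.310. Fry's directional test also called 0 (smallest adjusted p = 0.118), and its mixed test called 4: AHR targets, absorptive colonocytes, oxidative phosphorylation, and the NRF2 and oxidative-stress genes. In the last list 1 member rose and 11 did not pass, with 1 rising adjusted over the list alone. The remaining lists did not pass camera. Enteric neuron and glia markers had a median of 0.93, immediate-early and heat-shock genes 0.43, monocyte and macrophage markers 0.42, NRF2 genes 0.27, mitochondrially encoded genes 0.21, interferon-response genes -0.51 and epithelial junction genes -0.55. For innate cytokines (median 0.18, mean -0.076), B cells (0.067, -1.45), endothelium (0.058, -0.29), matrix metalloproteinases (-0.038, 0.018) and proliferation (-0.037, -0.057), the median, mean and test direction differed in sign. Camera's direction was down for the first 3 of these and up for the last 2. Adjusted over the list alone, 1 member was lower in each of the innate cytokine, B-cell, macrophage and neutrophil lists and 1 was higher in the immediate-early list.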

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

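Alternatives chosen after the data were seen are those without rRNA-like and mitochondrial genes, with protein-coding genes only, above background and with background subtracted. Of the 20 genes with the largest changes, 6 (Hoxd13, Fabp2, Tmigd1, Slc9a3, Reg4 and Tgm3) passed in all 19 alternatives, and all 20 kept their direction wherever they were tested. Kept directions are weak evidence here, since the rule that named these genes required groups without overlap. At this depth 1 count equals 0.340 to 0.609 CPM. In simulated counts with the depth, number and dispersion trend of these libraries, 1.49% of 2-fold and 89.4% of 8-fold changes were recovered. Those genes were drawn independently without gene-specific spread, so recovery in the real data may be lower. The share of depth in this was not tested.

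The gene count of 229 became 1327 without a filter, 148 at 10 CPM in 2 samples, 354 without mitochondrial, haemoglobin and immunoglobulin genes, 565 with DESeq2, 688 with limma on log2(TPM + 1), 657 at an adjusted p under 0.1, 362 without rRNA-like and mitochondrial genes, 144 above background and 107 with background subtracted. Leaving out 1 library gave 36 to 499, where a lone vehicle library was assumed to vary like the others. The cause was not tested, except that a looser threshold passes more genes by construction. The median log2 fold change of all genes was -0.018, and -0.14 with upper-quartile scaling, -0.39 with log2(TPM + 1) and -0.47 with log2(TPM + 0.1).

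Transcript calls went from 0 to 675 without a filter and 441 with DESeq2. List calls went from 12 to 0 with an estimated correlation and 0 with fry, and stayed within 1.5 times otherwise. The estimate was 0.89 for smooth-muscle and 0.85 for goblet-cell markers, but 0.012 for tubulin and 0.0035 for xenobiotic metabolism genes. The last value lies below the preset 0.01, yet camera's unadjusted p for that list went from 0.00413 to 0.0578. A larger correlation therefore does not account for the loss of every list. Replicate numbers 1 and 2 occur in both groups, and samples sharing a number had deviations correlated at 0.1698 and 0.147, over too few pairs to pair the samples. With the replicate number as a block, 639 genes (324 higher and 315 lower, 49.3% lower, so without the excess of lower calls), 12 lists and 0 transcripts were called. Propyzamide replicate 3 has no partner in vehicle, so its block term absorbs that library. The group effect of the block fit therefore rests on replicates 1 and 2 alone, with few residual degrees of freedom. In that fit the medians of the C/EBP, fibroblast, xenobiotic and NF-kB target lists were 0.059, 0.42, 0.27 and -0.43.

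Over all alternatives, 1525 values of genes and lists kept their direction and side of the threshold, 105 lost a call, 135 gained one and 22 turned. With limma on log2(TPM + 1) the log2 fold changes of Slc10a2, Lgr5 and Cidec were 2.80, -2.02 and 2.30, as a pseudocount shrinks changes of low levels by construction. Directions turned only for results that did not pass. Rela was -0.031 with upper-quartile scaling, -0.010 at 10 CPM in 2 samples, -0.27 and -0.29 with limma at pseudocounts 1 and 0.1, and -0.10 to 0.34 with 1 library left out. Nfkbia was -0.31 and -0.32 with limma, and -0.28 to 0.85 with 1 library left out. Ahr was -0.084 and -0.16 with limma, and -0.37 to 0.79 with 1 library left out. Tiparp was -0.10 and -0.14 with limma, and Nqo1 was -0.42 to 2.00 with 1 library left out. Camera's direction for AHR targets turned above background (median 0.33) and without vehicle replicate 2, propyzamide replicate 1 or propyzamide replicate 3 (medians 0.50, 0.067 and 0.42), while medians with 1 library left out ran from 0.067 to 1.61. That for NF-kB targets turned without a filter (median -0.23) and without vehicle replicate 2 (0.25), while these medians ran from -0.35 to 0.25. Without a filter the AHR median was -0.70 while its direction stayed up. The cause was not tested.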

Other observations

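Hoxb13, Hoxd11, Atp12a and Apoa1, the gene lists of this part, the division of the Hox sum by cluster and the tests with genes above background, 1 background threshold for both directions or background subtracted were chosen after results had been seen.

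Of 6 tested posterior Hox genes, which pattern the hind part of the body, 3 fell (Hoxb13, Hoxd11 and Hoxd13), 0 rose and 3 did not pass. Hoxb13 fell from 165 and 179 CPM in vehicle to 23.1, 16.4 and 4.87 CPM in propyzamide (-3.50 ± 0.48 on the log2 scale; edgeR adjusted p = 0.00605). Hoxd11 had 63 counts in vehicle and 0 in propyzamide, 32.8-fold lower against the floor of 3 counts over the group (edgeR adjusted p = 0.0149), a call lost without vehicle replicate 2. Hoxd10, Hoxa10 and Hoxa13 stood at -3.49, 0.94 and 0.77 (edgeR adjusted p = 0.138, 0.289 and 0.534). Atp12a, the colonic proton-potassium pump, fell from 114 and 155 to 34.7, 26.7 and 4.26 CPM (edgeR adjusted p = 0.0417), and its call was lost without vehicle replicate 1 (0.183), vehicle replicate 2 (0.233), propyzamide replicate 2 (0.0663) or propyzamide replicate 3 (0.0598), and with background subtracted (0.0568). Apoa1, an apolipoprotein of small-intestinal enterocytes, had 0 counts in vehicle and 2.72, 59.0 and 13.4 CPM in propyzamide (edgeR adjusted p = 0.0504), and passed in 10 of 17 alternatives. Of 6 tested small-intestinal enterocyte genes 0 passed, with a median of 1.27, and of 7 distal sodium transport genes 1 fell, with a median of -0.48. Of 6 tested mesothelial genes 0 passed (median 1.27), of 3 middle Hox genes 0 passed (median 0.24) and of the squamous genes 1 was tested and did not pass (0.086).

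The first pattern is that genes such as Hoxd13 and Hoxb13 were lower while Slc9a3, Slc10a2 and Fabp2 were higher. A different share of epithelium as the whole cause was not decided by the test as set beforehand, since a bound given below was not met. It predicts that epithelial genes move together by about the same amount, which Slc9a3 and Fabp2 did not do. The 12 pan-epithelial genes had a median of 0.053 with an interquartile range of 0.53. Each of the 20 named genes, picked for their size, changed by at least 4.24. The bound set beforehand for small-intestinal enterocyte genes was not met (median 1.27, interquartile range 2.47). The comparison with 4.24 was not among the bounds set beforehand. Scaling centres most genes near 0, so the pan-epithelial median cannot show whether the share itself differed. Smooth-muscle and adipocyte markers had medians of 2.06 and 2.85, so a different share of these tissues in the pieces stays open. Pieces from different colon segments remain a candidate explanation, but the test set for it came out against it as written: the summed CPM of 9 further posterior Hox genes overlapped between the groups, with propyzamide at 1.06 times vehicle. That sum mixed 3 HoxA genes, at 17.8 and 20.99 CPM in vehicle against 33.0, 37.0 and 36.5 in propyzamide, with 2 HoxD genes, at 12.0 and 14.8 against 0, 0 and 3.04, so the sums of the clusters lay on opposite sides, where the prediction had assumed 1 direction; this was seen after the sums and not tested. Segment and treatment cannot be told apart, since the segment is not given and 1 index sequence went with each group, and an effect of propyzamide stays open.

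The second pattern is that vehicle libraries had more genes with a count. Depth is argued against, since after thinning the lower vehicle library still had 1.43 times the genes of the highest propyzamide library. Background reads from DNA or unspliced RNA are a candidate explanation: the lower vehicle library exceeded the highest propyzamide library by 14.8 percentage points in receptor genes with a count. Background estimated this way came to 9.61% and 7.36% of counts outside rRNA-like and mitochondrial genes in vehicle, and 0.477%, 4.91% and 1.81% in propyzamide. The source of these reads was not tested.

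The third pattern is that lower calls outnumbered higher ones among the 229 genes, which did not hold in all alternatives and turned to 35 higher and 20 lower without vehicle replicate 2. Among genes above background 60.4% of calls were lower (87 of 144), against 63.8% of all calls, and 52.3% were lower with background subtracted (56 of 107). The Wilson 95% interval of the first share, 52.3% to 68.0%, reaches past the lower bound of 53.8% set beforehand. That interval treats genes of the same 5 libraries as independent and is therefore too narrow. Over all genes the lower share was 49.3% with the replicate block and 86.6% with limma on log2(TPM + 1). The block leaves propyzamide replicate 3 out of the group effect, and the limma run had no scaling between libraries beyond TPM. The threshold behind the 60.4% was higher for lower genes, since expected background was 3.02 times larger in vehicle. With 1 threshold for both directions, 5 times the larger background, 39 lower and 0 higher calls lay under it, leaving 107 lower and 83 higher (56.3% lower). Background reads could account for part of the excess, and whether they account for all of it stays open. No biological explanation was tested.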
